A study of Rattus norvegicus with 4 samples.

How the data were processed

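RNA of NR8383 rat macrophages exposed to zinc iron oxide was measured on 4 arrays, 1 per biological replicate, all with the same dose of 17 µg/mL and exposure of 4 h in the labels. The arrays carry 1 colour (Cy3). Per the file headers, the deposited intensity values were read from the scans with Agilent Feature Extraction 11.0.1.1, which subtracts background and corrects spatial trends within an array to give the processed signal. No normalization between arrays is recorded in the headers. The array design names an older rat genome build, and no coordinates were used. All 4 arrays lay on 1 slide that was scanned in 1 session.

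The deposited value table of the series was compared with the scanner files. Each of its 4 columns equals the median pixel intensity of the same array on all 62976 spots, so its scale is linear and it is neither centred nor normalized. The column medians were 54, 604.5, 219 and 46 for replicates 1 to 4. The planned estimate of each gene's departure from a centre chosen by the authors, and its gene list test, need a centred table and were not run.

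Analysis started from the processed intensity. Control spots and spots marked as non-uniform or as population outliers were left out, which removed 832, 946, 1109 and 868 gene spots on replicates 1 to 4. Spots of 1 probe were averaged on the log2 scale, and 213 probes with no spot left on an array were dropped. The 75th percentile of each array over all probes was subtracted. A probe was counted as well above background by the scanner's flag. Probes were named through the accession in the files, without versions, and the RefSeq gene table of the GRCr8 assembly. Of 45598 probes, 21109 were named and 24489 were not. Names were found for 19258 of 20504 probes with NM accessions, 1317 of 7704 with XM, 424 of 7249 with XR, 110 of 117 with NR and 0 of 6958 with Ensembl transcripts. A gene's level is that of its probe with the highest mean signal, and a gene counts as above background if any of its probes was. In 905 of 3640 genes with several probes, the probes disagreed on detection on replicates 1 and 4.

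The genes of 25 lists, 413 entries in all, were fixed before the data were examined, and 387 entries were measured. They cover zinc and iron handling, NRF2 targets, heat shock, the unfolded protein and integrated stress responses, cytokines, NF-kB targets, immediate early genes, the inflammasome, lysosome and autophagy, the interferon response, sterol and lipid metabolism, p53, the cell cycle, hypoxia, the proteasome, reference genes and markers of 8 cell types. By a rule set at the same time, the text names the first measured members of a list as listed, of which 4 were taken once the files had been read, and the 10 genes of largest variance ratio among those past the threshold, of which there were none. Values of 2 members of the sterol and lipid list are not reported here.

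Spread between replicates was given as SD over the 4 arrays. Genes with extra spread were tested by an F test of each variance against a prior variance with a trend on mean level, fitted with limma 3.58.1, with Benjamini-Hochberg adjustment and a threshold of 0.05. List deviations were set against 10000 random lists of the same size drawn within 20 bins of mean signal, with a two-sided p. The same random lists give percentiles for the difference between replicates 1 and 4, as a description of those samples. Both procedures were tested on simulated data. The variance test made 0 false calls and recovered 10 of 100 genes at 3 times and 28 of 100 at 5 times the usual SD among 6813 genes, or 37 and 69 with a robust prior, which made 3 false calls. The list procedure was run on differences shuffled over 7379 genes. It found a shift of 0.5 log2 units in 14 immediate early genes in 19 of 20 runs and a shift of 0.25 in 3 of 20. There were 2 to 5 false list calls over the 20 runs of each size. Shuffling removes correlation between members of a list, and random lists are drawn gene by gene. The false-call counts and the p of a list therefore hold for lists of unrelated genes only.

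Alternatives planned beforehand were the other detection flag, other numbers of arrays, normexp background correction with an offset of 50, quantile normalization, the percentile over detected probes, no filter on dim probes, the mean of all probes of a gene, a robust prior and leaving out each replicate. Normexp used the median spot signal in place of the mean signal. Added after seeing the data were replicates 1 and 4 alone, replicates 2 and 3 alone, scaling on the 3 brightest spike-in probes, a detection threshold of 3 SD above the dimmest spike-in probe, leaving out each replicate for list levels and list deviations, and the difference of lists between replicates 1 and 4 over genes read by a single spot, without and with correction of each spot for its neighbours. The shifts of single levels without each replicate, and the gap over range under other scalings, were added as well. The dimmest spike-in probe is here the one with the lowest signal on replicates 1, 3 and 4. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3. The number of arrays, 4, limits the precision of all levels.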

Results

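NR8383 is a rat macrophage line that was started from lung lavage and serves as a model of the alveolar macrophage. Cells of this line, labelled with 20 passages, had been exposed for 4 h to 17 µg/mL of zinc iron oxide, a particle of zinc ferrite, and their RNA was measured on 1-colour rat gene expression arrays. The series is described as a comparison of exposed with unexposed cells, with 4 biological replicates of each. The 4 arrays of exposed cells are reported here and the control arrays were not analysed here. The values therefore describe which genes were detected in exposed macrophages, at what level and with what spread, and no gene is said to rise or fall with exposure.

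Each array held 58717 gene spots for 45598 probes, of which 21109 could be given a gene symbol. These probes stood for 16581 genes, and 16526 had a value on every array. The share of gene spots well above background was 47.0% on replicate 1, 89.5% on replicate 2, 70.5% on replicate 3 and 41.6% on replicate 4. The median processed signal was 13.5, 542, 133 and 7.37 intensity units in the same order. No gene spot was saturated.

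The arrays were set side by side on control RNAs that are added to each sample in known steps and do not come from the cells. On replicates 1 and 4 the dimmest of the 10 spike-in probes had a log2 signal of 1.80 and 1.91, and 0 of its 35 spots lay well above background on each. On replicates 2 and 3 the same probe had a log2 signal of 9.11 and 6.85, with 35 and 34 spots well above background. The brightest spike-in probe differed less, at 15.45, 14.45, 15.10 and 15.00 for replicates 1 to 4. The scanner software marked 2, 8, 5 and 2 of its 11 quality metrics as out of range on replicates 1 to 4. The spike-in slope was out of range on replicate 2 alone, at 0.69. The software placed the spike-in detection limit of replicates 1 and 4 inside its range and that of replicates 2 and 3 outside it. Detection is therefore given below for all 4 arrays and for replicates 1 and 4, a choice made after the control spots were seen.

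**Figure D1:**
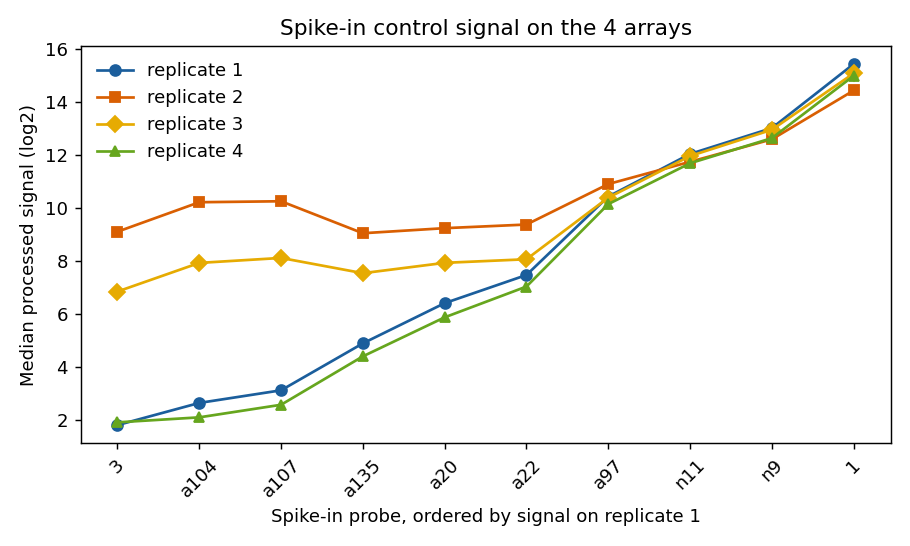
Median processed signal (log2) of the 10 spike-in probes, ordered along the horizontal axis by their signal on replicate 1, with a line for each of the 4 arrays. At the dimmest probe replicates 2 and 3 lie at 9.11 and 6.85 and replicates 1 and 4 at 1.80 and 1.91, while at the brightest probe the 4 arrays lie between 14.45 and 15.45.

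On each of the 4 arrays at least 1 probe, not necessarily the same one, was well above background for 7030 of 16526 genes (42.5%). The count was 7598 genes (46.0%) on both replicate 1 and replicate 4. A further 4588 genes were well above background on replicates 2 and 3 and on neither of the other arrays. A further threshold was the signal, on the same array, of the spike-in probe that was dimmest on replicates 1, 3 and 4. On replicate 2 another spike-in probe read slightly lower, at a log2 signal of 9.05 against 9.11. When a gene had to exceed the first of these probes by 3 SD of its spots, 2546 genes (15.4%) passed on all 4 arrays. On replicates 1 to 4 singly, 9986, 3778, 3370 and 8843 genes passed, against 8646, 15146, 12478 and 7652 by the flag. The threshold was thus looser than the flag on replicates 1 and 4 and stricter on replicates 2 and 3. Counts of genes that pass it on all arrays are limited by replicates 2 and 3. Levels below are log2 signals relative to the 75th percentile of the array, as mean ± SD over n = 4 arrays, and levels of different probes are not compared. Spots of the dimmest spike-in were flagged on replicates 2 and 3, so the flag there does not separate a dim gene from such signal. The mean and SD of a dim gene, such as Fos or Fosb, include its values on those arrays. The genes named for each list are its first 4 measured members, unless another choice is stated, and a gene that was not well above background on an array is given no level.

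Genes of zinc handling were well above background on replicates 1 and 4 for 11 of 16 measured members, and on all 4 arrays for 9. Mt1, a metallothionein that binds zinc, had a level of 7.74 ± 1.93, with 9.24 on replicate 1 and 9.32 on replicate 4. Mt2A, a second metallothionein, had a level of 4.01 ± 2.19. Slc30a1, which exports zinc across the plasma membrane, had a level of 2.25 ± 1.62. Mt3 was not well above background on replicate 1 or 4. On the threshold set by the dimmest spike-in, 4 members of the list passed on all arrays.

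Of 17 measured genes of iron handling, 11 were well above background on replicates 1 and 4 and 10 on all 4 arrays. Fth1 and Ftl1, the heavy and light chains of the iron store ferritin, had levels of 8.59 ± 1.46 and 9.14 ± 1.62. Tfrc, the transferrin receptor, had a level of 2.76 ± 2.35, with 4.50 on replicate 1 and 5.06 on replicate 4. Slc40a1, the iron exporter ferroportin, was not well above background on replicate 1 or 4.

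Targets of NRF2, the transcription factor of the oxidative stress response, were well above background on all 4 arrays for 18 of 19 measured members. Hmox1, which breaks down haem, had a level of 7.36 ± 2.02, with 8.82 on replicate 1 and 9.19 on replicate 4. Gclc, the catalytic subunit of glutathione synthesis, had a level of 2.51 ± 2.06. Nqo1, a quinone reductase, had a level of 0.47 ± 0.97. Gclm was not well above background on any array and was the exception in the list. On the threshold set by the dimmest spike-in, 11 members passed on all arrays.

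**Figure D2:**
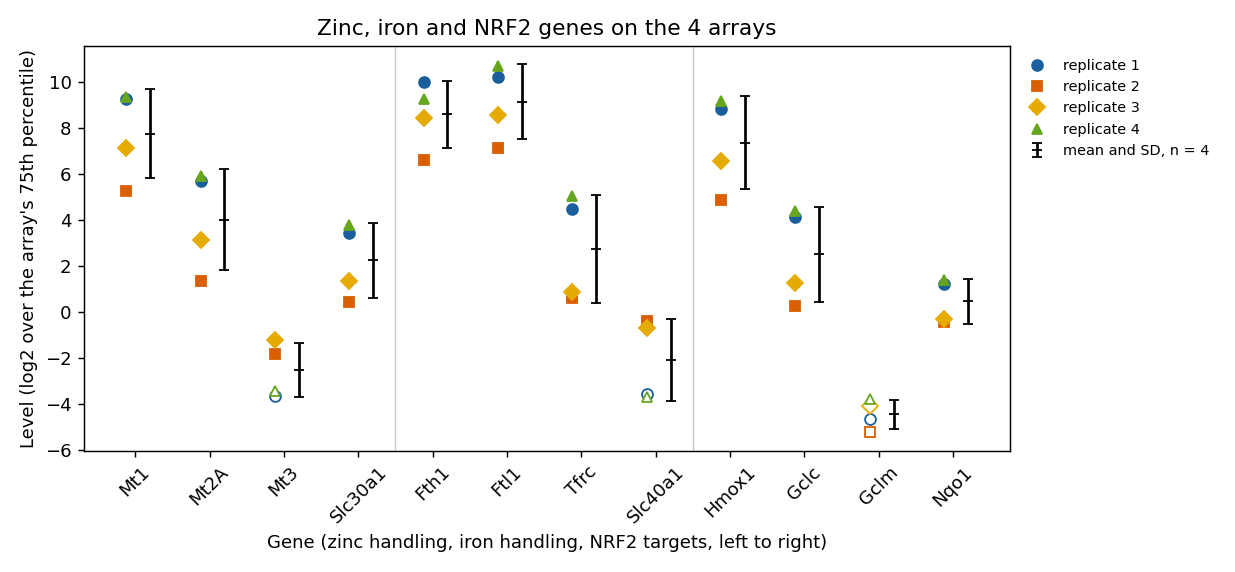
Levels (log2 relative to the 75th percentile of the array) of the first 4 measured members of the zinc, iron and NRF2 lists, with a symbol for each of the 4 arrays, open where the gene was not well above background, and a bar for the mean and SD (n = 4). Mt1 lies at 9.24 and 9.32 on replicates 1 and 4, and its SD of 1.93 goes with lower values on replicates 2 and 3 and is 0.30 with scaling on spike-ins.

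Heat shock genes were well above background on all 4 arrays for 13 of 15 measured members. Hspa8, a constitutive chaperone, had a level of 8.20 ± 1.81, and Hsp90aa1 had a level of 6.21 ± 1.96. Hsph1 had a level of 0.03 ± 0.36. For Hspa1a, the inducible counterpart of Hspa8, the 2 probes disagreed, since the brighter was well above background on replicates 2 and 3 and the other on all 4 arrays, so no level is given. Of 18 measured genes of the unfolded protein and integrated stress responses, 17 were well above background on all 4 arrays. Atf4, the transcription factor at the centre of the integrated stress response, had a level of 5.15 ± 1.82, and Atf3 had a level of 3.27 ± 2.08. Ddit3 and the endoplasmic reticulum chaperone Hspa5 had levels of 1.22 ± 1.76 and 3.75 ± 1.96. With the threshold of the dimmest spike-in, 6 heat shock genes and 10 genes of the stress responses passed on all arrays.

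Cytokine and chemokine genes were well above background on all 4 arrays for 15 of 27 measured members, and the same number was found on replicates 1 and 4. Il1a and Il1b, both interleukin-1 genes, had levels of 3.00 ± 1.90 and 3.28 ± 1.64. Tnf had a level of 3.21 ± 1.63, with 4.43 on replicate 1 and 4.72 on replicate 4. Il6 was well above background on replicate 2 and on no other array. The monocyte chemoattractant gene Ccl2, named after its values were seen, had a level of 4.99 ± 1.94, and Cxcl1, named in the same way, was not well above background on any array. For 7 of the 27 members the signal was well above background on replicates 2 and 3 and on neither replicate 1 nor 4. The threshold of the dimmest spike-in was passed by 7 members on all arrays.

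NF-kB target genes were well above background on all 4 arrays for 10 of 14 measured members. Nfkbia, the inhibitor that NF-kB itself induces, had a level of 2.76 ± 1.19, and Nfkbie had a level of 0.94 ± 0.26. Nfkb1 and Nfkb2, which encode subunits of the factor, had levels of -1.24 ± 0.16 and 2.10 ± 1.68. Of 10 inflammasome genes, 8 were well above background on replicates 1 and 4 and 7 on all 4 arrays. The sensor Nlrp3 had a level of 0.58 ± 0.97, the adaptor Pycard 2.21 ± 1.63 and the protease Casp1 1.32 ± 1.58, while Casp4 had a level of -0.39 ± 1.03. Interferon response genes were well above background on replicates 1 and 4 for 15 of 18 members and on all 4 arrays for 12. Isg15 had a level of 1.17 ± 0.81 and Ifit3 a level of -0.55 ± 1.27. Ifit1 was not well above background on replicate 1 or 4, and Ifit2 was not on replicate 3. On the threshold of the dimmest spike-in, 5 NF-kB targets, 2 inflammasome genes and 3 interferon response genes passed on all arrays.

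Immediate early genes, which are transcribed within minutes of a stimulus, were well above background on replicates 1 and 4 for 14 of 23 measured members and on all 4 arrays for 13. Fos had a level of -0.36 ± 0.46 and Fosb a level of -0.21 ± 0.56. Fosl2 had a level of 0.33 ± 0.33, and Fosl1 was well above background on replicate 2 and on no other array. The threshold of the dimmest spike-in was passed by 4 members on all arrays.

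Genes of the lysosome and autophagy were well above background on all 4 arrays for 19 of 22 measured members. The membrane proteins Lamp1 and Lamp2 had levels of 4.43 ± 1.95 and 3.53 ± 2.04, and the proteases Ctsb and Ctsd had levels of 7.27 ± 2.01 and 8.16 ± 1.84. Proteasome genes were well above background on all 4 arrays for 21 of 21 measured members, with Psma1 at 3.95 ± 1.87, Psma2 at 3.00 ± 1.73, Psma3 at -0.07 ± 1.68 and Psma4 at 3.45 ± 1.81. Sterol and lipid genes were well above background on replicates 1 and 4 for 18 of 19 members and on all 4 arrays for 17. Hmgcs1 and Sqle, enzymes of cholesterol synthesis, had levels of 2.12 ± 1.49 and 1.76 ± 2.15. On the threshold of the dimmest spike-in, 7 sterol and lipid genes passed on all arrays.

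Cell cycle genes were well above background on all 4 arrays for 18 of 18 measured members. The proliferation marker Mki67 had a level of 1.89 ± 1.05, and the mitotic cyclin Ccnb1 had a level of 3.20 ± 1.78. The cyclins Ccna2 and Ccne1 had levels of 2.61 ± 1.96 and 2.00 ± 1.96. Genes of the p53 and DNA damage response were well above background on all 4 arrays for 11 of 15 members. Cdkn1a, the cell cycle inhibitor p21, had a level of 3.73 ± 2.05, and Mdm2 had a level of 1.17 ± 1.27. Gadd45a and Gadd45b had levels of 2.08 ± 1.32 and 0.09 ± 0.53. Hypoxia and glycolysis genes were well above background on all 4 arrays for 13 of 16 members. The glucose transporter Slc2a1 had a level of 3.31 ± 1.64, Hk2 a level of -0.23 ± 0.75 and Pfkfb3 a level of 1.65 ± 1.67, while Vegfa was not well above background on replicate 1 or 4. With the threshold of the dimmest spike-in, 3 p53 genes and 4 hypoxia genes passed on all arrays. The 12 commonly used reference genes were well above background on all 4 arrays, with Actb at 7.78 ± 2.05, Gapdh at 8.24 ± 1.98, Ppia at 8.55 ± 1.79 and Rplp0 at 8.53 ± 1.46.

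Markers of the alveolar macrophage were well above background on all 4 arrays for 17 of 23 measured members. The macrophage glycoprotein Cd68 had a level of 5.51 ± 1.77, the scavenger receptor Msr1 a level of -0.39 ± 0.47 and the mannose receptor Mrc1 a level of 0.36 ± 2.00. Marco, a further scavenger receptor, was not well above background on replicate 1 or 4. On the threshold of the dimmest spike-in, 8 markers passed on all arrays.

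Markers of other cell types, apart from erythroid ones, were mostly not well above background on replicates 1 and 4, where 46.0% of all named genes were. The counts on both of these arrays were 1 of 13 epithelial markers, 1 of 12 markers of T and NK cells, 1 of 5 B cell markers and 2 of 10 markers of neutrophils and mast cells. They were 3 of 9 endothelial markers, 1 of 10 markers of fibroblasts and smooth muscle and 3 of 5 erythroid markers. The members counted were Foxj1 among epithelial markers, Lck among T and NK cell markers, Pax5 among B cell markers, S100a8 and Camp among neutrophil and mast cell markers, Pecam1, Cdh5 and Vwf among endothelial markers, Dcn among fibroblast markers, and Hba-a1, Epor and Klf1 among erythroid markers. Foxj1, Lck, Dcn and Klf1 lie outside the first 4 of their lists and were chosen after their values were seen. Pecam1, which macrophages also express, had a level of 1.05 ± 1.13, Cdh5 a level of -0.04 ± 1.06 and Vwf a level of 4.00 ± 1.77. Pax5 had a level of 1.01 ± 0.97, S100a8 a level of -1.28 ± 0.38 and Camp a level of 0.71 ± 0.86. The epithelial genes Epcam, Krt8, Krt18 and Krt19 and the fibroblast genes Col1a1, Col1a2, Col3a1 and Pdgfra were not well above background on replicate 1 or 4. Of the T cell genes, Cd3e, Cd3g and Cd8a were not well above background on replicate 1 or 4, and Cd3d was not on replicate 4. On replicate 2 the counts were 12 of 13 epithelial markers and 12 of 12 markers of T and NK cells, and on replicate 3 they were 11 and 11. Without replicate 4, 2 epithelial markers and 2 markers of T and NK cells were well above background on all remaining arrays. On the threshold of the dimmest spike-in, 0 epithelial, T and NK, B, neutrophil and mast cell or fibroblast markers passed on all arrays, and 1 endothelial and 1 erythroid marker did.

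**Figure D3:**
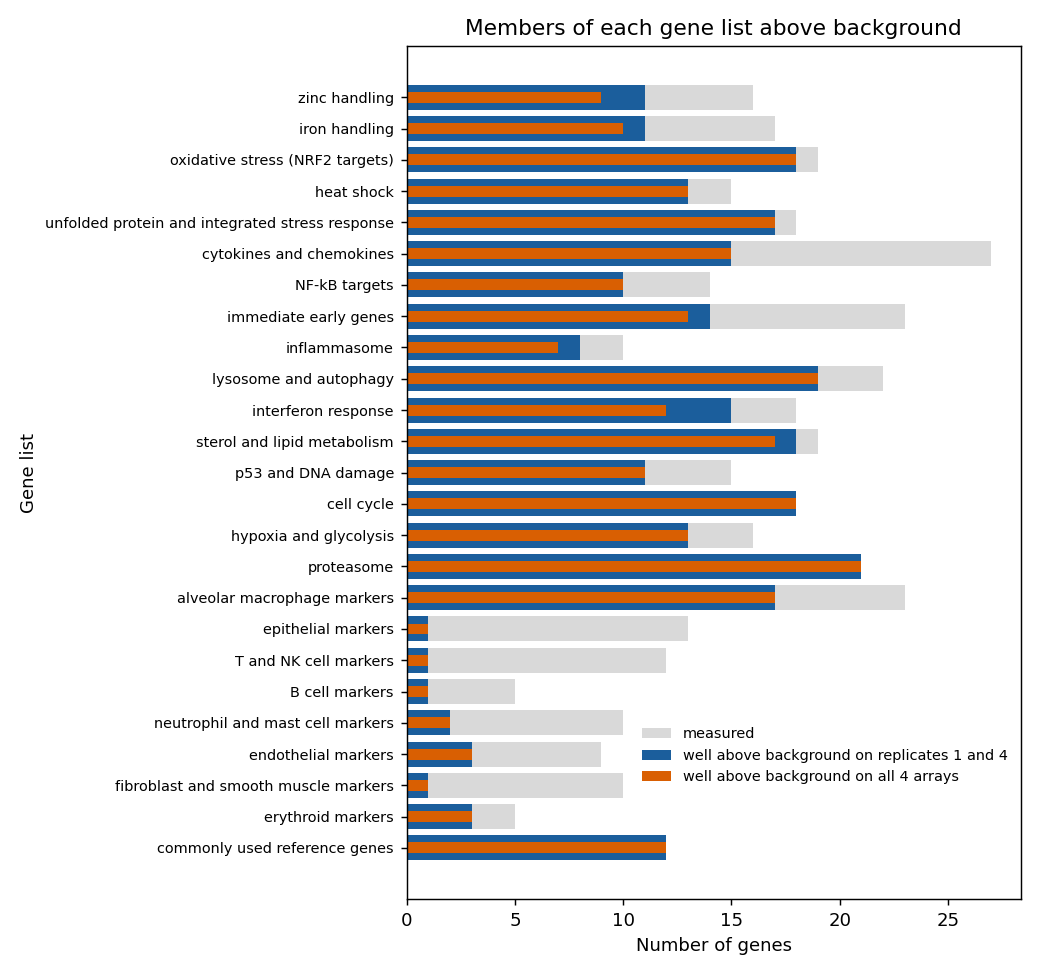
Number of genes (horizontal axis) in each of the 25 gene lists that were measured (grey), well above background on replicates 1 and 4 (blue) and well above background on all 4 arrays (orange). The proteasome list reaches 21 of 21 genes and the epithelial list 1 of 13.

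The spread between replicates was computed for 6813 genes whose chosen probe was well above background on all 4 arrays. The median SD was 1.55 log2 units, and 10% of genes had an SD under 0.45. The median absolute difference was 0.20 between replicates 1 and 4, 0.86 between replicates 2 and 3, and 3.00 between replicates 1 and 2. The last was largely an offset in the same direction for most genes, since the median signed difference was 3.00 as well. This offset depended on the scaling, since with spike-in scaling the median of replicate 1 minus replicate 2 was -0.84. Across 12931 probes well above background on all arrays, Pearson's r was 0.989 for replicates 1 and 4 and 0.802 for replicates 1 and 2, where probes are not independent replicates. Repeated spots of 1 probe on an array had a median SD of 0.10, 0.09, 0.12 and 0.16 on replicates 1 to 4. Scaling the arrays on probes well above background on all arrays gave a median SD of 0.43, and using replicates 1 and 4 alone gave 0.15. The SD of a single gene depended on the scaling as well. With scaling on the 3 brightest spike-in probes it went from 1.93 to 0.30 for Mt1 and from 1.68 to 0.51 for Nfkb2, but from 0.16 to 2.09 for Nfkb1, from 0.26 to 2.14 for Nfkbie and from 0.33 to 1.68 for Fosl2. The SDs beside the levels therefore do not rank genes by their spread between cultures. The levels themselves depended on the arrays and probes used. Over 69 genes among the first members of the lists whose chosen probe was well above background on all arrays, leaving out replicate 2 raised the level by a median of 0.60 log2 units (-0.53 to 0.89), to 8.93 for Hspa8 and 6.95 for Hsp90aa1. Without replicate 1, 3 or 4 the median shift was -0.42, 0.27 or -0.48, and with replicates 1 and 4 alone it was 1.36, with 46 genes higher by more than 1 log2 unit. Averaging all probes of a gene lowered 9 levels by more than 1 log2 unit, to 6.72 for Hspa8, 6.94 for Gapdh, 2.47 for Lamp2, 1.17 for Ccna2, 1.44 for Vwf, 0.59 for Cdkn1a, 1.56 for Tnf, -0.34 for Pfkfb3 and -0.87 for Nlrp3.

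Genes with more spread between the replicates than other genes of like signal were sought with an F test against limma's trended prior. None of the 6813 genes passed an adjusted p of 0.05, and 311 had an unadjusted p under 0.05. With a robust prior 0 genes passed as well, and 224 had an unadjusted p under 0.05. Each of these counts is a smaller share of the genes than the 0.05 that chance alone gives. In simulated data of the same size, the test recovered 28 of 100 genes given 5 times the usual SD and 10 of 100 given 3 times. With the robust prior it recovered 69 and 37, with 3 false calls. Spread of 3 times the usual SD was thus mostly missed with either prior, and that of 5 times with the first prior. The simulation drew noise independently for each array and held no offset shared by genes, so these rates may not hold here.

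The lists were also tested for a joint deviation of each array from the other 3. Of 80 pairs of a list and an array, 0 passed an adjusted p of 0.05 in a permutation test against 10000 random lists matched on signal. The lowest adjusted p was 0.32, for the proteasome list on replicate 3, whose median lay 0.22 log2 units below that of the random lists.

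Replicates 1 and 4 were then set against each other for 7379 genes well above background on both, with 1 sample on each side and hence no test between samples. The immediate early genes had a median difference of -0.56 log2 units, replicate 1 minus replicate 4, with 12 of 14 members lower on replicate 1. This median lay below those of all 10000 random lists matched on signal. Scaling on the 3 brightest spike-in probes raised replicate 1 against replicate 4 by the same amount for every gene, so that the list's median became 0.02 and that of its random lists went from 0.01 to 0.59. Differences below are relative to the 75th percentile, and those of the stress lists change sign with spike-in scaling and with normexp background correction, although each stays below the median of its random lists. Dusp1, a phosphatase of the MAP kinases, was at -0.67 on replicate 1 and 0.59 on replicate 4. Fos was at -0.91 and 0.21, Fosb at -0.59 and 0.63 and Jun at 3.03 and 3.99, while Myc was at 3.49 and 2.44. These genes were chosen after their values were seen. The lists of heat shock, NRF2 and iron handling had median differences of -0.30, -0.22 and -0.33, at the percentiles 0.43, 0.53 and 0.64 of their random lists. These were the next lowest percentiles and were chosen for that, and none of the 3 lists passed an adjusted p of 0.05 in the permutation test against random lists (0.065 for each). These calls depended on the setting, since NRF2 targets passed with normexp (adjusted p 0.022) and heat shock over its 9 members read by a single spot (0.0025). The unfolded protein and integrated stress responses lay at the percentile 6.12 with a median difference of -0.13, and at the percentile 0 with -0.49 over the 10 members read by a single spot. Zinc handling lay at the percentile 30.1 with -0.08. Across single genes, 150 differed by more than 2-fold, 85 of them higher on replicate 1 and 65 lower. Among the 77 of the higher genes that were read by a single spot, the median distance to the nearest other such spot was 3.61 spot positions, against 13.9 in random sets of spots.

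**Figure D4:**
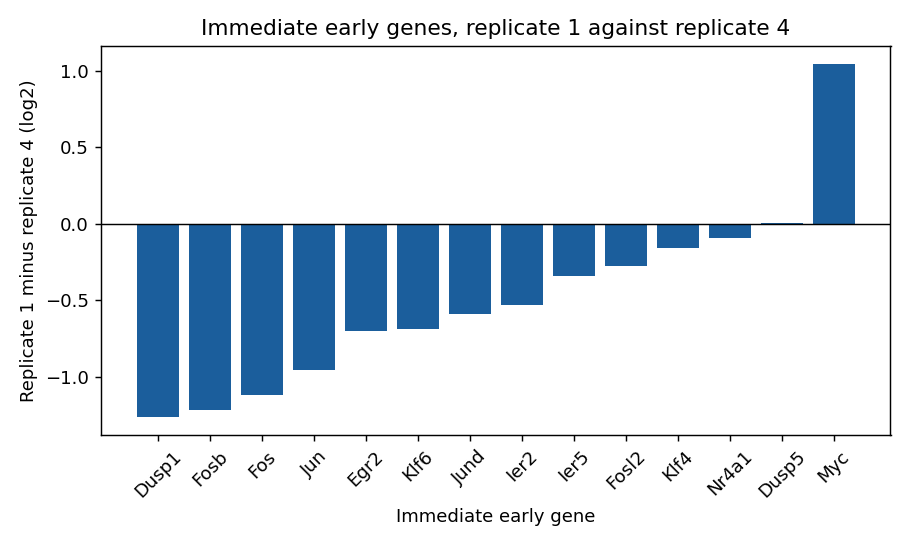
Difference in level between replicate 1 and replicate 4 (log2, vertical axis) for the 14 immediate early genes well above background on both arrays, with a bar for each gene. Bars reach from -1.27 for Dusp1 to 1.05 for Myc, and 12 of 14 lie below 0, where scaling on spike-ins instead of the 75th percentile raises the median from -0.56 to 0.02.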

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

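Among 107 per-array values and named genes examined, 2 had 1 array far from the other 3 by Dixon's ratio of gap to range. The chance rate of about 1 in 20 assumes 4 independent draws from 1 distribution. It need not hold here, since replicates 1 and 4 differ from replicates 2 and 3 by an offset shared by most genes. For Fosb, an immediate early gene, the ratio was 0.854, with replicate 4 at 0.63 and replicates 1 to 3 at -0.59, -0.41 and -0.45. For Cdh5, a cadherin of endothelial cells, the ratio was 0.904, with replicate 2 at 1.54 and replicates 1, 3 and 4 at -0.71, -0.49 and -0.51. Both ratios depended on the scaling, against a critical value for 4 samples that only Cdh5 passed again, with normexp (0.841). For Fosb the ratio was 0.655 with normexp, 0.479 with quantile normalization, 0.362 with the percentile over detected probes and 0.597 with spike-in scaling. For Cdh5 it was 0.802, 0.533 and 0.679 in the last 3 of these. The comparison over scalings was chosen after the ratios were seen. No explanation was tested for either gene on its own.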

How the results depend on the processing

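Settings that use replicates 1 and 4 alone, replicates 2 and 3 alone, scaling on spike-ins or the spike-in threshold, and those leaving out a replicate for list levels and deviations, were chosen after the data were seen. Genes detected on all arrays numbered 7030, against 15474 on at least 1 array and 2546 above the dimmest spike-in probe by 3 SD, which on replicates 2 and 3 is a higher signal by construction. Leaving out a replicate gave 7065 to 7736. The median SD of 1.55 became 1.13 with normexp, 0.84 with quantile normalization, 0.43 with the percentile over detected probes, 0.79 with spike-in scaling, 0.15 on replicates 1 and 4, 0.45 on replicates 2 and 3, and 1.20 to 1.69 without 1 replicate (1.20 without replicate 2). Much of the SD of 1.55 was an offset between arrays shared by most genes. Replicate 1 lay above replicate 2 by a median of 3.00, with a median absolute difference of 3.00 as well. Against replicate 3 these values were 2.09 and 2.10. With spike-in scaling the median of replicate 1 minus replicate 2 was -0.84, in the other direction, and that of replicate 1 minus replicate 3 was 0.61. The median SD thus depends on the point used for scaling and does not give the spread between cultures. No cause was tested beyond these values.

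Genes with extra spread numbered 0, and 0 to 2 without 1 replicate: 2 without replicate 2 (Spns3 and Spem1), 1 with the mean of a gene's probes (Spns3) and 3 on replicates 1 and 4 (Hpf1, Spcs1 and Nr2c2ap, all higher on replicate 1). The cause was not tested beyond a correction for neighbouring spots. After it, the difference was 3.85 for Hpf1 (3.73 before) and had fallen to 2.64 for Nr2c2ap (3.41 before). No corrected value is given for Spcs1. Pairs of a list and an array past the threshold numbered 0 (0 to 0 without 1 replicate), 1 with quantile normalization (iron handling, 0.56 higher on replicate 4) and 1 on replicates 1 and 4 (immediate early genes). The median level over list members was 0.93, 2.00 on replicates 1 and 4, 0.51 to 1.40 without 1 replicate, and -4.92 with spike-in scaling, which moves the zero of the scale by construction. Of 69 levels of named genes well above background on all arrays, 9 fell by more than 1 log2 unit with the mean of probes. That 0 rose follows largely from the rule, since a level is read from the brightest probe of its gene. With normexp the shifts ranged from -0.88 to 0.72. Of the 25 list counts, 20 moved with the spike-in threshold, and 2 without replicate 4 (epithelial and T and NK cell markers, 2 each).

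The plan's slide block was not run, since all arrays share 1 slide, and the departure from the authors' centre was not run, since the table is not centred. No paired analysis was possible because the samples form a single group. Signal over background limits dim genes on replicates 2 and 3, where the most dilute spike-in reads 554 and 115 against 3.49 and 3.75 on replicates 1 and 4.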

Other observations

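Chosen after the result was seen were the tests of the high dim signal, of the stress lists, of bright members alone, of other probes of the same genes, of lists over members read by single spots and of counts after correction for neighbouring spots. The tests of the place of spots, and of the immediate early genes under other normalizations and after correction for neighbours, were fixed before their results. The labels put all samples in 1 group, and no biological explanation was tested as a factor of the design.

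Probes that were not well above background on replicates 1 and 4, 27725 in number, had a median signal of 348 on replicate 2 and 75.7 on replicate 3, against 3.82 and 3.55 on replicates 1 and 4. More transcripts in replicates 2 and 3, or RNA from other cell types, is argued against by spike-in probes, which no cell RNA makes. For the 4 that were dimmest on replicates 1 and 4, replicates 2 and 3 were higher on average by at least 3.65 log2 units. A higher scanner gain is argued against by the 3 brightest spike-in probes, which differed by -0.17 log2 units on average, while the amount of labelled cell RNA was not tested. Signal that probes take up whatever RNA they were made for predicts correlated dim probes between replicates 2 and 3, where Spearman's rho was 0.767. Between replicates 1 and 4, which lack the high dim signal, rho was 0.539. Transcripts shared by 2 samples would correlate as well, so rho cannot decide on this explanation. Probes are also not independent replicates. The negative control spots rose less, with median signals of 23.0 and 12.9 on replicates 2 and 3 against 3.45 and 3.34, so what this signal consists of stays open.

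Immediate early genes were lower on replicate 1 than on replicate 4 by 0.57 log2 units beyond random lists of like signal (excess -0.57). A scaling difference shared by all genes moves a list and its random lists alike, so the excess cannot decide on it. With spike-in scaling the excess stayed at -0.57, while the list's own median went from -0.56 to 0.02. A trend with signal, beyond what the matching on signal takes up, is argued against as the whole source. The excess was -0.45 with quantile normalization and -0.31 with normexp, at the percentiles 0 and 0.01 of the random lists. The normexp value lies close to the bound of -0.3 set for this test. A local defect is argued against, since the excess over the 7 members read by single spots was -0.72. It was -0.80 after each spot was corrected for its neighbours within 10 rows and columns. Noise of dim spots was examined through the 6 members with a signal of at least 200 on both arrays, whose excess was -0.57. That the cultures differed in their response or handling may be a candidate explanation, but with 1 sample on each side it cannot be told apart from other differences between 2 samples: the heat shock, iron and NRF2 lists, picked after their values were seen, had an excess in the same direction, nearest 0 at -0.19 for the NRF2 targets, and which lists passed the threshold depended on the setting.

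Against random lists, the adjusted permutation p of heat shock, iron handling and NRF2 targets was 0.065 each. NRF2 targets passed with normexp (0.022, excess -0.23) and had 0.11 with quantile normalization and 0.34 over the 12 members read by a single spot, or 0.61 after correction for neighbours. Heat shock passed over its 9 members read by a single spot (0.0025, excess -0.44, and 0.020, excess -0.40, after correction) and had 0.082 with normexp and 0.11 with quantile normalization. The unfolded protein and integrated stress responses had an excess of -0.12 (0.31), with 0.12 under normexp and 0.24 under quantile normalization, and -0.49 over the 10 members read by a single spot (0.0019), or -0.58 after correction (0.0019). Cytokines passed after correction alone (0.047, excess -0.29), with 0.082 to 0.16 in the other settings. Iron handling did not pass in any of these settings (0.065 to 0.18).

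Genes more than 2-fold higher on replicate 1 than on replicate 4 numbered 85 and included Hpf1 (4.44 against 0.71), Nr2c2ap (2.55 against -0.86) and Spcs1 (4.71 against 1.58). A different amount of transcript is argued against for most of the 11 such genes with a further probe well above background on both arrays, since the median difference of the further probes was -0.13 log2 units (SD 0.49), with 2 exceptions above 0.5, Gapdh-ps1 and RT1-N3. A local defect on either array is consistent with the place of the spots, since the median distance to the nearest other such spot was 3.61 spot positions against 13.9 in random sets (percentile 0). After correction for neighbouring spots, the number of genes read by a single spot that were more than 2-fold higher went from 77 to 34, with Hpf1 still at a difference of 3.85, and that of lower genes from 62 to 58. The spots of the lower genes were not closer than in random sets (percentile 44.4), and 9 of 10 lower genes with a further probe were lower by it too (median -0.27, with 4 beyond 0.5), among them Slpi, an inhibitor of leukocyte proteases, with differences of -1.87 and -1.76 for its probes.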
